A study of Mus musculus with 8 samples.

How the data were processed

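RNA was measured in 8 mammary gland samples, 4 from MMTV-Cre;Sox9 flox/flox and 4 from MMTV-Cre;Sox9 flox/+ virgin females. Total RNA was extracted with a Qiagen RNeasy Mini kit and labelled in a core facility, per the labels' protocols. Each sample was hybridised to its own Affymetrix Gene 1.0 ST array. The deposited values are intensity on a linear scale, made by the authors with PLIER in Affymetrix Expression Console 1.0, per the submitters' processing notes. PLIER sums the probes of a probe set by a model of their affinities. The background correction and the normalization between arrays that went with it are not given in the sources used here. The deposited table holds 35557 probe sets and gives no detection calls, so values near 0 cannot be told from background. Each of its columns matched the identifier of a sample, whose title gave genotype and replicate, and the number of unmatched columns is 0.

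Probe sets were named through the platform annotation supplied with the table: 21789 had 1 gene symbol, 1621 had several and 12147 were unnamed. The first kind entered the tests. Of these 21698 matched the RefSeq gene table of assembly GRCm38.p6 by gene identifier, which changed 0 symbols and gave the order of genes along chromosomes; the remaining 91 kept the annotation's symbol. Coordinates were not used. For the 999 genes with several probe sets the brightest on average stood for the gene, which left 19938 genes.

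Values were offset by 16 and taken to log2. The 10th, 50th and 90th percentiles of the arrays spread by up to 0.245, 0.145 and 0.105, above a tolerance of 0.1 fixed beforehand, so the arrays were quantile normalized. All intensities in the text are after this step unless called deposited. The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust options), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Differences are flox/flox minus flox/+ on the log2 scale with limma's standard error, folds are those differences taken back from log2 with the offset still in, and levels are means of intensity with their SD. The difference of Sox9 and of list means was also tested with a 2-sided exact permutation test of the 70 assignments of the arrays, whose smallest p is 0.0286.

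Gene lists for cell types and pathways of the gland, 31 in all, were written before the data were examined, as were the tests, the named-gene rule and most alternatives. The lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists. Lists with fewer than 5 measured genes were not tested, which left 30. Of the 615 different genes in the lists 563 were measured. Another 6 lists, for the clock, glucocorticoid targets, mesothelium and macrophages, were written after the leading genes were seen and appear only in the closing section. A list score is the mean z-score of its members. The text names Sox9, genes past the threshold whose values did not overlap between genotypes (at most 12 in each direction), and, in a direction with fewer than 5, the 8 genes with the smallest p among those without overlap. From each list it names up to 4 members past the threshold adjusted over the list alone, or the 2 with the smallest p where none passed. It also names any gene that a count of 5 or fewer refers to.

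The labels do not say whether equal replicate numbers in the titles mark shared litters or days, and the numbers were not used to pair samples. No 2 arrays held identical values, with median absolute log2 differences between 0.12 and 0.173 for a pair of arrays. Alternatives were the replicate number as a block, the values as deposited, median centring, offsets of 1 and 64, dropping the lowest 1 in 3 genes by mean level, all probe sets, eBayes with trend and robust options, array weights, B cell or luminal scores as covariates, each array left out, an unmoderated statistic, a threshold of 0.1, a fold of at least 1.5, camera with an estimated correlation, limma's fry, and the mean over a gene's probe sets.

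The scripts were tested on simulated arrays with the means and SDs of the 19938 genes. For this comparison of 4 with 4 arrays, of 50 genes changed by 0.5 on the log2 scale 74% were recovered, of 50 changed by 1 94%, and of 50 changed by 2 and of 50 changed by 4 100% each. Of the calls 3.05% were false. With no change simulated 1 gene and 0 lists passed. Genes were drawn independently of each other, so the simulation does not test camera where the genes of a list move together. In the real arrays the estimated correlation was 0.464 for the cell cycle list and 0.705 for the mitochondrial respiration list. The recovery shares hold for 200 changed genes and a cell cycle list shifted by -0.35 in the same simulation.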

Results

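Gene expression was measured in mammary glands of 8 virgin female mice, 5 weeks old, to ask how the loss of Sox9 alters the gland at puberty. Sox9 is a transcription factor best known from cartilage and from progenitor cells of several epithelia. All 8 mice carried MMTV-Cre, a recombinase driven by the promoter of the mouse mammary tumour virus and active in mammary epithelium. In 4 mice both Sox9 copies were flanked by recombination sites (flox/flox). The other 4 kept a wild-type copy beside a floxed one (flox/+) and served as controls. The tissue was the part of the fourth gland that lies toward its lymph nodes, so fat, stroma and immune cells were measured together with the ducts. Each gland came from its own mouse and was hybridised to its own Affymetrix Gene 1.0 ST array, and the number of arrays limits the precision. The deposited intensities had medians between 159 and 178 per array.

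Sox9 itself (probe set 10382328, chromosome 11) was lower in the flox/flox glands, in all 4 of them below the lowest control. Its intensity was 323 ± 35.7 (SD, n = 4) in flox/flox and 410 ± 35.1 (SD, n = 4) in flox/+ glands. The controls read 424, 448, 401 and 366, and the flox/flox glands 298, 356, 287 and 351. The log2 difference was -0.33 ± 0.09 (SE, 95% interval -0.53 to -0.13), so that flox/flox glands held 79.5% of the control level. A 2-sided exact permutation test of this difference gave p = 0.0286, the smallest p that 4 against 4 arrays allow, whereas limma's p of 0.00415 became 0.256 after adjustment over all 19938 genes tested. The labels do not say which part of the gene is deleted, so it is not known whether the probes lie inside it.

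Of the 8 genes that passed the test 6 were higher in the flox/flox glands. Rnase2a, a member of the eosinophil-associated ribonuclease family, rose from 5.16 ± 2.07 to 798 ± 474 (SD, n = 4 per genotype). Mrgprg, a Mas-related G protein-coupled receptor, rose 20.6-fold, from 99.9 ± 11.3 to 2517 ± 994. Smpd3, which encodes a neutral sphingomyelinase, rose 4.57-fold, and Daglb, a diacylglycerol lipase, rose 2.50-fold. Duox2, a dual oxidase that produces hydrogen peroxide, rose 2.49-fold, and the lipid-binding protein gene Sec14l1 rose 1.44-fold. Kera, which encodes the matrix proteoglycan keratocan, fell from 109 ± 13.8 to 65.9 ± 3.22, and Kif11, a motor protein of the mitotic spindle, fell from 145.4 ± 7.496 to 91.4 ± 4.73.

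These 8 genes, 6 higher and 2 lower, were the genes with a limma adjusted p under 0.05. The log2 differences were 4.36 ± 0.24 (SE) for Mrgprg with adjusted p = 4.2e-05, 2.19 ± 0.26 for Smpd3, 1.32 ± 0.18 for Daglb, 1.32 ± 0.12 for Duox2 with adjusted p = 0.00479, 0.53 ± 0.07 for Sec14l1, -0.61 ± 0.08 for Kera and -0.59 ± 0.07 for Kif11 with adjusted p = 0.0172. For each of the 8 the values of the genotypes did not overlap. For all 6 higher genes the lowest flox/flox value lay in flox/flox replicate 2, which read 1351 for Mrgprg and 98.3 for Rnase2a. Control values of Rnase2a lay between 3.01 and 7.59, near the bottom of the scale and not told from background, so its size has no firm value: the log2 difference was 4.83 ± 0.60 with an offset of 16 (adjusted p = 0.031), 6.63 with an offset of 1 and 3.29 with an offset of 64. The related Rnase2b read 226 ± 60.6 in flox/flox and 195 ± 38.7 in flox/+ glands, without passing the test. Of all genes tested 1175 (5.89%) had values without overlap between the genotypes, against 2.86% by chance. At an unadjusted p under 0.05 there were 2047 genes, 958 higher and 1089 lower, against 997 expected on average by chance. Among the other divisions of the 8 arrays into 4 and 4 the highest count was 1858. That division set flox/+ replicates 1 and 2 and flox/flox replicates 2 and 4 against the rest, so an excess over 997 does not by itself mark the genotypes. With 1 array left out at a time, Mrgprg and Duox2 stayed past the threshold in 8 of 8 fits, Kif11 and Smpd3 in 4, Sec14l1 and Rnase2a in 2, and Kera and Daglb in 1. The count of genes fell to 4 without flox/+ replicate 1 or flox/flox replicate 1, fell to 2 without flox/+ replicate 4 or flox/flox replicate 4, and rose to 21 without flox/flox replicate 3. The count was 1, Mrgprg, when the unnamed probe sets of the table were tested too, and with an unmoderated 2-sample statistic it was 0, with 1897 genes at an unadjusted p under 0.05.

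**Figure D1:**
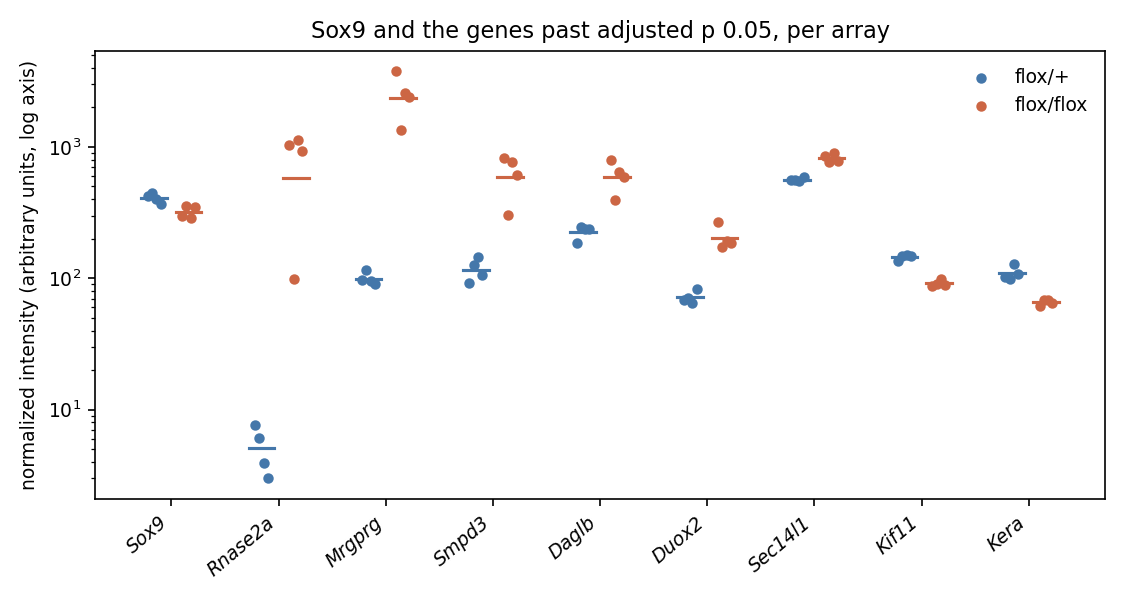
Normalized intensity (arbitrary units, log axis) of Sox9 and of the 8 genes past adjusted p 0.05 in each of the 4 flox/+ (blue) and 4 flox/flox (orange) glands. Points are arrays, and lines are means taken on the log2 scale after adding 16 and brought back to intensity; Mrgprg lies at 1351 to 3776 in flox/flox and at 90.5 to 116 in flox/+ glands.

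Since only Kera and Kif11 passed in the lower direction, the 8 lower genes with the smallest unadjusted p and no overlap between the genotypes are given by value. Besides that pair they were Prom1, a surface protein of hormone-sensing luminal cells (-0.66 ± 0.09, adjusted p = 0.0501), the kinetochore motor Cenpe (-0.60 ± 0.09), Bpifa3 (-0.41 ± 0.07), the guanylate-binding protein Gbp2b (-0.76 ± 0.12), the proliferation marker Mki67 (-0.64 ± 0.11) and the topoisomerase Top2a (-0.68 ± 0.12), each as a log2 difference with its SE from 4 glands per genotype. Prom1 read 97.2 ± 10.1 in flox/flox and 163 ± 17.4 in flox/+ glands (SD, n = 4). Another probe set of Top2a differed from the chosen brighter probe set, with a log2 difference of -0.06.

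Cell cycle genes were lower in the flox/flox glands. All 34 measured members of the cell cycle list had negative log2 differences, with a median of -0.34, and the list fell in limma's camera test (adjusted p = 2.85e-23; adjusted p = 0.466 with an estimated correlation). The members that fell when adjusted over the list alone numbered 21, among them Kif11, Cenpe, Mki67 and Top2a, while over all genes tested 1 did, Kif11. Mki67 read 216 ± 31.6 in flox/flox against 345 ± 38.1 in flox/+ glands (SD, n = 4), and Cenpe 58.3 ± 8.11 against 96.4 ± 6.80. The mean of the list differed between the genotypes by -0.35 ± 0.08 (SE over arrays). Without flox/+ replicate 2, the array with the highest B and T cell markers, the median was -0.38. Across arrays the fibroblast and matrix score moved with the cell cycle score in most glands. The scores were 1.265 and 1.033 in flox/+ replicate 3, 0.556 and 0.825 in flox/+ replicate 4 and -1.162 and -1.072 in flox/flox replicate 2. In flox/flox replicate 3 they were 0.187 and 0.131, and in flox/flox replicate 4 -0.319 and -0.552. They differed in size in flox/flox replicate 1 (-0.188 and -1.043). Their signs differed in flox/+ replicate 1 (-0.261 and 0.439) and flox/+ replicate 2 (-0.079 and 0.24).

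Genes of mitochondrial respiration lay slightly higher in the flox/flox glands, each of the 23 measured members with a positive difference and a median of 0.18. The list rose in the camera test (adjusted p = 1.24e-10; adjusted p = 0.583 with an estimated correlation). The mean z-score of the list was lowest in flox/+ replicate 3 (-1.61) and highest in flox/flox replicate 1 (1.40), and the brown and beige adipocyte score was lowest and highest in the same glands (-0.967 and 1.474). Without flox/+ replicate 3 the median was 0.11, with the list still past the threshold. Adjusted over the list alone 7 members rose, among them cytochrome c (Cycs, 0.30 ± 0.08 SE), the complex III subunits Uqcrc1 (0.28 ± 0.08) and Cyc1 (0.27 ± 0.08), and the citric acid cycle enzyme Idh3a (0.31 ± 0.09).

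Lists for fat synthesis and for brown and beige adipocytes passed as higher in flox/flox, and the white adipocyte list did not pass. Of the fatty acid and sterol synthesis genes 18 of 20 had positive differences, with a median of 0.20 (camera adjusted p = 0.000262; adjusted p = 0.583 with an estimated correlation), and adjusted over the list alone no member passed, with 5 at an unadjusted p under 0.05. The members with the smallest p were Insig1, a brake on sterol synthesis (0.58 ± 0.21 SE), and the transketolase gene Tkt (0.26 ± 0.09). The sterol synthesis gene Hmgcs1, also among these 5, was lower (-0.25). Across arrays the fat synthesis score moved with the white adipocyte score in part. Both were highest in flox/flox replicate 2 (1.09 and 1.136) and lowest in flox/+ replicate 3 (-1.086 and -0.648). They were -0.588 and 0.513 in flox/+ replicate 4, and 0.613 and -0.151 in flox/flox replicate 3. Brown and beige adipocyte genes had a median of 0.38 over 14 members (camera adjusted p = 0.000524; adjusted p = 0.583 with an estimated correlation). The mean z-score of this list was 1.474 in flox/flox replicate 1 but -0.418, 0.006 and 0.254 in the other flox/flox glands, against -0.967 to 0.161 in the controls, and without flox/flox replicate 1 the median was 0.25 (adjusted p = 0.0399). Of these genes 1 rose when adjusted over the list alone, the fatty acid elongase Elovl3, at 499 ± 166 in flox/flox and 145 ± 116 in flox/+ glands (SD, n = 4). White adipocyte genes had a shift short of the threshold (median 0.04, camera adjusted p = 0.145), but adjusted over the list alone Gpd1, which links sugar breakdown to triglyceride synthesis, rose by 0.38 ± 0.09 and the fatty acid binding protein Fabp5 by 0.54 ± 0.14.

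The fibroblast and matrix list was lower in the flox/flox glands. It had a median of -0.27 over 27 members, 19 of them negative, and fell in the camera test (adjusted p = 5.52e-06; adjusted p = 0.583 with an estimated correlation). Adjusted over the list alone 7 members fell, among them the basement membrane collagens Col4a1 (-0.39 ± 0.09 SE), Col4a2 (-0.35 ± 0.09) and Col15a1 (-0.46 ± 0.12) and the fibrillar collagen Col5a2 (-0.45 ± 0.13), while Col6a2 (0.03) and Col14a1 (0.05) did not pass. The mean z-score of the list was highest in flox/+ replicate 3 (1.265) and lowest in flox/flox replicate 2 (-1.162). Col4a1 read 1431 ± 160 in flox/flox and 1874 ± 134 in flox/+ glands (SD, n = 4).

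The granulocyte and mast cell list was higher in the flox/flox glands. It had a median of 0.14 over 20 members and rose in the camera test (adjusted p = 0.000524; adjusted p = 0.466 with an estimated correlation). The mean z-score of the list was 0.871 in flox/flox replicate 1 but -0.094 in flox/flox replicate 2, below the 0.036 of flox/+ replicate 3. Adjusted over the list alone 3 members rose: Fcer1a, a chain of the high-affinity IgE receptor (0.69 ± 0.13 SE), the mast cell tryptase Tpsb2 (0.41 ± 0.11) and the eotaxin receptor Ccr3 (0.66 ± 0.18). The eosinophil genes Prg2 (-0.17), Epx (0.14) and Siglecf (0.15) and the mast cell tryptase Tpsab1 (-0.06) did not pass. Nor did the mast cell genes Mcpt4 (0.42), Cma1 (0.33) and Cpa3 (0.34), which were positive. Of the 20 members 14 were positive and 6 negative. Fcer1a read 89.9 ± 21.9 in flox/flox and 48.5 ± 1.77 in flox/+ glands (SD, n = 4). The eotaxin gene Ccl11, in the list of ductal growth signals, also rose when adjusted over the list alone (0.64 ± 0.15), from 553 ± 83.0 to 878 ± 191, although that list as a whole did not pass (median 0.08, camera adjusted p = 0.158).

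The Notch list was past the threshold with a small shift, a median of 0.08 over 16 members (camera adjusted p = 0.0281; adjusted p = 0.583 with an estimated correlation). No member passed when adjusted over the list alone, and 1, the Notch target Hes1 (0.41 ± 0.14 SE), had an unadjusted p under 0.05. The Notch transcription partner Rbpj was at 0.18 ± 0.09, and its other probe set at 0.44. The call of the list ended without any 1 of flox/+ replicates 2, 3 and 4 and flox/flox replicates 2 and 3 (adjusted p between 0.0542 and 0.0926), and also with array weights (0.0546), with the B cell score as covariate (0.0741) and without the lowest 1 in 3 genes (0.0557).

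Exact permutation tests of the list means gave p = 0.0286 for the cell cycle and the granulocyte and mast cell lists, 0.0571 for mitochondrial respiration, 0.114 for the brown and beige adipocyte and Notch lists, 0.143 for fibroblasts and matrix and 0.229 for fatty acid and sterol synthesis, so that 2 of the 7 lists past the camera threshold had p under 0.05 in this test. The skin and hair keratinocyte list, which did not pass camera (adjusted p = 0.0648), also had an exact permutation p of 0.0286, and its camera adjusted p was 0.0268 with the values as deposited and 0.0321 with median centring.

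Thus 7 of the 30 tested lists passed, 5 higher and 2 lower, while over all genes tested 1 list member, Kif11, passed, against 49 adjusted over the list alone and 121 at an unadjusted p under 0.05, of 581 list entries. With an estimated correlation between genes 0 lists passed in camera and 3 had an unadjusted p under 0.05, and in fry 0 passed and 5 had an unadjusted p under 0.05. Of the 35 ways to split the 8 arrays into 4 and 4, 29 gave at least 7 lists, the real split included, so the number of lists alone does not set the genotypes apart. The count of lists moved to 11 without flox/+ replicate 3, and to 12 without flox/+ replicate 4 or flox/flox replicate 4.

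**Figure D2:**
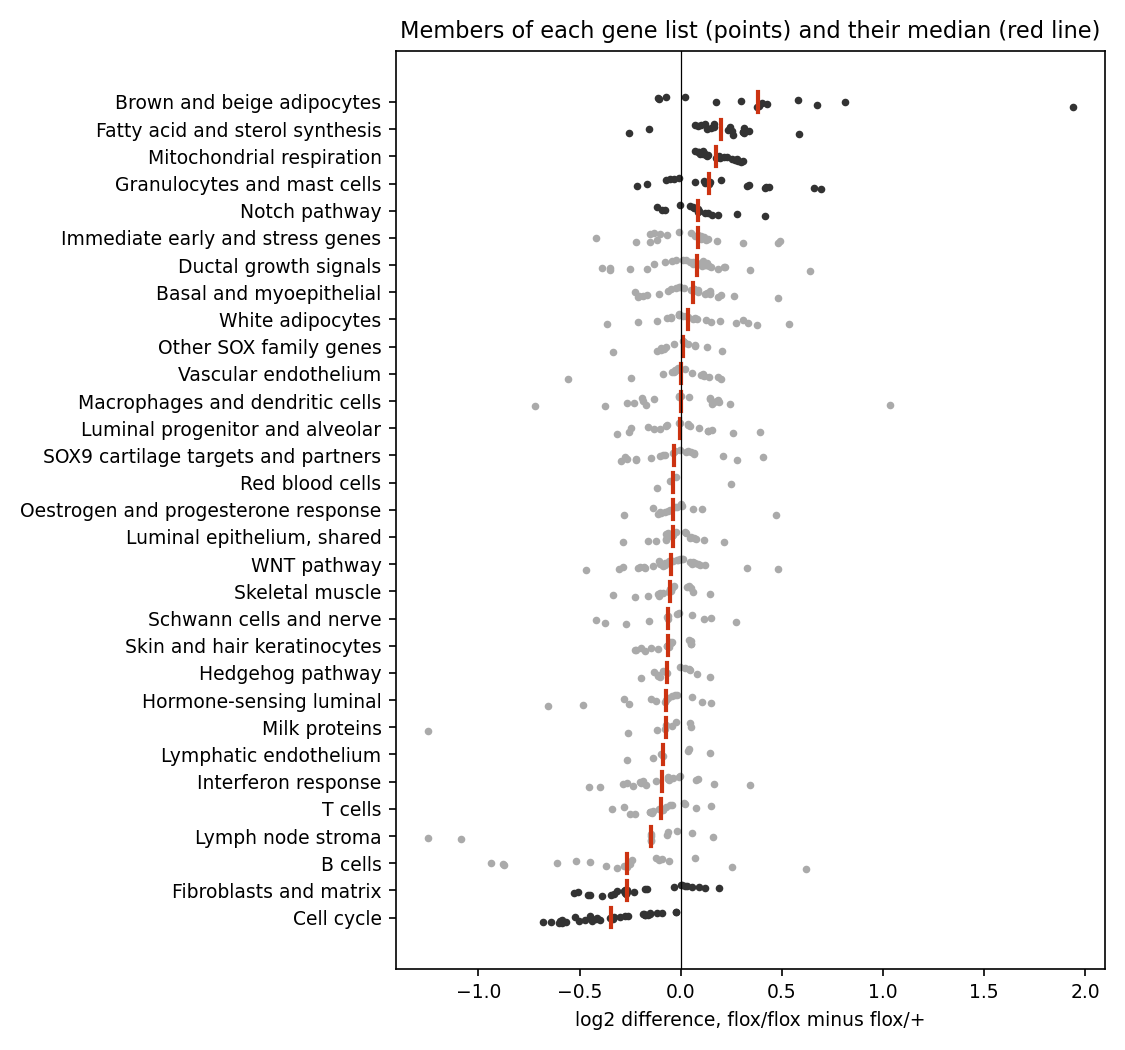
Log2 differences (flox/flox minus flox/+) of the measured members of all 31 gene lists, a point per gene, with the list's median as a red line. Black points mark the 7 lists past the threshold in the camera test and grey points the others; the cell cycle list lies at the bottom with a median of -0.34 and the brown and beige adipocyte list at the top with 0.38.

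Epithelial markers showed no shift that passed as a list in the main setting. The shared luminal list passed in 1 of 22 alternatives and the hormone-sensing luminal list in 2 of 22. Within the flox/flox glands the shared luminal score ran from -0.974 in replicate 1 to 0.995 in replicate 4. The shared luminal epithelium genes had a median of -0.04 over 21 members (camera adjusted p = 0.667), and adjusted over the list alone 1 fell, the tight junction protein Cldn1 (-0.28 ± 0.07 SE). The mean of this list differed by -0.02 ± 0.09 (SE over arrays). Hormone-sensing luminal genes had a median of -0.07 (adjusted p = 0.122), with 2 members that fell when adjusted over the list alone, Prom1 and the luminal transcription factor Gata3. Gata3 read 799 ± 188 in flox/flox and 1103 ± 63.98 in flox/+ glands (SD, n = 4). Luminal progenitor and alveolar genes had a median of -0.01 (adjusted p = 0.667), with Mfge8 at -0.31 ± 0.10 and the progenitor enzyme Aldh1a3 at 0.26 ± 0.08. Basal and myoepithelial genes had a median of 0.06 (adjusted p = 0.304), with the stem cell receptor Lgr5 at 0.48 ± 0.19 and the cadherin Cdh3 at 0.18 ± 0.08. Milk protein genes had a median of -0.07 (adjusted p = 0.206), and 1 of them, the fatty acid thioesterase Olah, fell when adjusted over the list alone (-0.26 ± 0.07).

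The list of SOX9 cartilage targets and partners had a median of -0.03 over 20 members, 12 negative and 8 positive (camera adjusted p = 0.212). The list passed as lower in 1 of 22 alternatives, without the lowest 1 in 3 genes (median -0.096, camera adjusted p = 0.00984). The collagens Col11a1 (-0.30 ± 0.07 SE) and Col9a2 (-0.22 ± 0.07) fell and the matrilin Matn1 (0.28 ± 0.07) rose when adjusted over the list alone. The collagens Col9a3 (-0.27), Col9a1 (-0.22), Col11a2 (-0.15) and Col2a1 (-0.28) were also negative, without passing. In this list 6 members had an unadjusted limma p under 0.05. Other SOX family genes had a median of 0.01 (adjusted p = 0.708), with Sox2 at -0.33 ± 0.13 and Sox4 at 0.20 ± 0.09. In the signalling lists the medians were -0.05 for the WNT pathway (adjusted p = 0.304), -0.07 for the Hedgehog pathway (adjusted p = 0.523) and -0.04 for the oestrogen and progesterone response (adjusted p = 0.504). Their members with the smallest p were the WNT inhibitor Apcdd1 (-0.47 ± 0.11) and Wnt5a (-0.30 ± 0.12), the Hedgehog receptor Ptch1 (-0.20 ± 0.08) and the effector Gli2 (0.15 ± 0.06), and the secreted proteins Igfbp5 (-0.28 ± 0.10) and Stc2 (0.47 ± 0.18), and no member of these lists passed when adjusted over the list alone, with 3, 2 and 2 at an unadjusted p under 0.05.

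Lymphoid markers set a single control gland apart. In flox/+ replicate 2 the B cell receptor component Cd79a read 1073 against 32.0 to 69.7 in the other 7 glands, and the endothelial mucin Glycam1 of lymph node venules read 4672 against 93.3 to 115. The mean z-score of that array was 2.002 for the B cell list, 1.93 for the T cell list and 0.95 for the lymph node stroma list. None of the 3 lists passed: the medians were -0.26 for B cells (camera adjusted p = 0.0933), -0.10 for T cells (adjusted p = 0.122) and -0.14 for lymph node stroma (adjusted p = 0.158). The B cell list passed in 7 of 22 alternatives, among them the values as deposited (adjusted p = 0.0268), median centring (0.0238) and the replicate block (0.0471), and the T cell list in 5 of 22, among them median centring (0.0365), whereas without flox/+ replicate 2 the medians were 0.09 for B cells and 0.04 for T cells and neither list passed. Members with the smallest p were the antigen presentation gene Cd74 (0.62 ± 0.17 SE) and the B cell coactivator Pou2af1 (-0.31 ± 0.13), the T cell genes Sh2d1a (-0.22 ± 0.10) and Cd3d (-0.25 ± 0.12), and Fut7 (-0.15 ± 0.07) and Il7 (-0.14 ± 0.07) among the stroma genes. Without flox/+ replicate 2 the number of genes past the threshold was 10 and the number of lists 6.

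Macrophage and dendritic cell genes had a median of 0.00 (camera adjusted p = 0.96), with the phagocytic receptor Timd4 at -0.72 ± 0.23 SE and the Fc receptor Fcgr1 at -0.37 ± 0.12. Interferon response genes had a median of -0.09 (adjusted p = 0.0933), with Ifit3 at -0.40 ± 0.14 and Irf7 at -0.45 ± 0.17, and passed in 6 of 22 alternatives, among them the values as deposited (adjusted p = 0.0374) and median centring (0.0365). Immediate early and stress genes had a median of 0.08 (adjusted p = 0.185), with Klf4 at 0.48 ± 0.14 and Klf6 at 0.31 ± 0.10. Vascular endothelium had a median of 0.00 (adjusted p = 0.582), with the tight junction gene Cldn5 at -0.56 ± 0.18 and the transcription factor Erg at 0.20 ± 0.08, and lymphatic endothelium a median of -0.09 (adjusted p = 0.299), with Reln at -0.26 ± 0.09 and Stab2 at -0.14 ± 0.10. Skeletal muscle had a median of -0.05 (adjusted p = 0.158; Tnnt3 at -0.23 ± 0.09, Mb at -0.11 ± 0.06) and Schwann cells and nerve -0.06 (adjusted p = 0.398; Ncmap at -0.27 ± 0.09, Nrn1 at -0.37 ± 0.13). Skin and hair keratinocytes had a median of -0.07 (adjusted p = 0.0648), with Krt1 at -0.18 ± 0.06 and Krt27 at -0.23 ± 0.09. The red blood cell list had 4 measured members and was not tested, with Hemgn at -0.12 ± 0.07 and Alas2 at 0.25 ± 0.22. For the luminal progenitor, other SOX family, vascular and macrophage lists the median, mean and camera direction differed in sign, each within 0.02 of 0.

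Genes near Sox9 on chromosome 11 were compared with other chromosomal windows, because the mice were a cross of C57BL/6 and FVB and a floxed allele travels with the genes around it. Among the 50 tested genes on each side of Sox9 limma called 0, with 11 at an unadjusted p under 0.05, against 10.3% of all genes. The median log2 difference of these 100 genes was -0.01, and their median absolute limma statistic lay at the 40.9th percentile of all such windows. Such a median can miss a change in several of the genes, so a strain effect on some of them stays open. Sec14l1, 1 of the 8 called genes, lies on the same chromosome, 96 tested genes from Sox9.

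The arrays separated by genotype along the principal component with the largest share of the variance, 25.1%, on which the 4 flox/+ glands lay on the other side from the 4 flox/flox glands (exact permutation p = 0.0286). The tissue identifiers of the genotypes share 0 initial letters, and the labels do not say what the letters stand for. If they mark cohorts, cohort and genotype cannot be told apart on this component or in the genes and lists above. Pairs of arrays correlated with r between 0.980 and 0.989 across genes, which are not independent replicates.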

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

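The tests of the cell cycle genes were chosen only after that result was seen, and the others in this part before.

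Among 214 sets of 4 values, from named genes and list scores within a genotype, 9 held a sample far from the other 3, where chance gives about 11. Rnase2a read 98.32 in flox/flox replicate 2 and 930.5 to 1136 in the other flox/flox glands. Mki67 read 263.4 in flox/flox replicate 3 and 198 to 205.3 in the others. In the controls Daglb read 186.4 in flox/+ replicate 1 against 236.2 to 247.4, Prom1 read 137 in flox/+ replicate 2 against 169 to 175.5, Sox2 read 281.7 in flox/+ replicate 4 against 394.7 to 417.3, and Krt27 read 133.2 in flox/+ replicate 1 against 107.2 to 108.9. The B cell score of flox/+ replicate 2 was 2.002 against -0.491 to -0.301, and its T cell score 1.93 against -0.505 to -0.104. The luminal progenitor and alveolar score of flox/flox replicate 4 was 0.399 against -0.135 to -0.0648.

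Of the 35 ways to divide the 8 arrays into 4 and 4, only the real 1 gave as many as 8 genes past the threshold. The highest of the others gave 1. A share of 1 in 35 is the smallest this check can reach, so it sets the real division apart without excluding chance. Nor does the check separate genotype from the initial letters of the tissue identifiers, which divide the arrays the same way. For the lists the real division did not stand out, since 29 of the 35 divisions gave at least its 7 lists. The highest of the others gave 16. That division set flox/+ replicate 1 and flox/flox replicates 1, 2 and 3 against the rest and gave 0 genes past the threshold in limma, with 920 at an unadjusted p under 0.05, so the arrays share structure that camera at a preset correlation calls in many divisions.

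Cell cycle genes were lower in flox/flox glands, with a list median of -0.344, while the largest size in any other division of the arrays was 0.333. That division set flox/+ replicates 1, 3 and 4 and flox/flox replicate 3 against the rest. The cell cycle score was 0.131 in flox/flox replicate 3, near the 0.24 of flox/+ replicate 2, and -1.072 to -0.552 in the other flox/flox glands. Lymph node tissue in flox/+ replicate 2 is argued against as the source, because without that array the median was -0.3815, further from 0 than with it. A smaller share of epithelium in the flox/flox pieces stays open: the luminal list differed by -0.0237, with 2 standard errors spanning -0.2 to 0.153. This range leaves out a luminal shift as large as the cell cycle list's mean of -0.352 but not a smaller loss. The list covers luminal cells as a whole, so it cannot show a loss confined to part of the epithelium. Separate cohorts cannot be told apart from genotype, since the tissue identifiers of the genotypes share 0 initial letters, flox/+ with 1 letter and flox/flox with 2. A shift in fibroblast content was not tested. The fibroblast and matrix score moved with the cell cycle score in most glands (1.265 and 1.033 in flox/+ replicate 3, but -0.261 and 0.439 in flox/+ replicate 1). Members of that list were divided, so its score does not measure fibroblast content alone. Dcn (0.0003), Mfap5 (0.01) and Pdgfra (0.02) hardly differed and Pi16 (0.19) was positive, while Pdgfrb (-0.23), Thy1 (-0.27) and Lum (-0.28) were negative. An effect of the flox/flox genotype on proliferation, the biological explanation that the design names, also remains untested.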

How the results depend on the processing

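The wider window around Sox9 was chosen after seeing the data, and the other alternatives before. Sox9 stayed lower and short of the threshold in all 20 alternatives, at -0.38 to -0.28 with each array left out and with adjusted p between 0.19 and 0.439. The window of 20 genes on each side had a median of -0.03 and that of 100 genes, which takes in Sec14l1, -0.02.

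Against 8 genes in the main setting, the count was 18 with median centring, 19 with offset 64, 17 with trend and robust options, 25 at a threshold of 0.1, 4 with offset 1, 3 without the lowest 1 in 3 genes, 1 with all probe sets and 0 with an unmoderated statistic (1897 at an unadjusted p under 0.05). With each array left out it ran from 2 to 21. The list count, 7, was 11 with median centring or the luminal score as covariate, ran from 6 to 12 with each array left out, and was 0 with an estimated correlation and with fry (3 and 5 at an unadjusted p under 0.05). The split of 5 higher and 2 lower lists became 5 and 5 with the values as deposited and 5 and 6 with median centring. The cause was not tested.

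With the replicate number as a block the counts were 8 genes, 4 of them shared with the unblocked fit, and 8 lists, and the adjusted p of Sox9 was 0.309. Pairs of equal number had correlated deviations between -0.204 and 0.209, and 3 of 8 arrays correlated best with their own number. These values show no pairing by number, but they cannot exclude a shared day or litter, on which the labels are silent. Of 1481 other values for 75 named genes 1396 kept their side of the threshold, and their direction where called. Of the rest 65 lost the call, 20 gained it and 0 reversed. Of 657 for lists 602, 22, 33 and 0 did so. Only genes and lists called in the main setting could lose a call or reverse, and a change of sign in the others counted as kept. All 65 losses fell on the 8 called genes. Mrgprg kept the call in 19 of 20 alternatives, Duox2 in 17 of 19, Kif11 in 12 of 19 and Smpd3 in 12 of 20. Rnase2a kept it in 10 of 19, Sec14l1 in 8 of 20, Daglb in 7 of 20 and Kera in 6 of 19. Of the 7 lists 6 kept the call in 20 of 22 alternatives and lost it with an estimated correlation and fry; the Notch list kept it in 12 and lost it without any 1 of 5 arrays. Lists that gained a call were B cells in 7 alternatives, interferon response in 6, T cells and skin in 5 each, hormone-sensing luminal and white adipocytes in 2 each, and ductal growth signals, immediate early genes, shared luminal epithelium, skeletal muscle, SOX9 cartilage targets and vascular endothelium in 1 each. Offsets matter most for dim genes: Rnase2a lay between 3.29 and 6.63.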

Other observations

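The genes in this part were chosen after their values were seen, except where lists are named as fixed; the tests of the clock, serosal and neighbouring genes were written before their results were seen, except that windows shortened at chromosome ends were admitted after the values around Rnase2a, Smpd3 and Daglb were known, because Mrgprg had no full window.

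Duox2 passed the test, and values of related genes are given beside it. The oxidase Duox1 (0.61 ± 0.11 SE) and the maturation factors Duoxa1 (0.73 ± 0.12) and Duoxa2 (0.31 ± 0.08) had values that did not overlap between the genotypes, and they did not pass after adjustment over all genes (limma adjusted p = 0.106, 0.0857 and 0.246). Duoxa1 read 268 ± 42.9 in flox/flox and 155 ± 21.8 in flox/+ glands (SD, n = 4).

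Some macrophage genes of type 2 immunity are given by value, without having passed over all genes tested. Retnla, a secreted product of alternatively activated macrophages, read 4609 ± 1493 in flox/flox and 1486 ± 594 in flox/+ glands (SD, n = 4; log2 difference 1.65 ± 0.30 SE, limma adjusted p = 0.106). The eotaxin Ccl24 was at 0.56 ± 0.12 and arginase Arg1 at 0.40 ± 0.13, and 10 of 11 alternatively activated macrophage genes were positive, 2 of the 11 also in the fixed macrophage list, with a median of 0.10 and an exact permutation p of 0.0857 for their mean. Ccl24 rose when adjusted over this list alone, and over all genes its adjusted p was 0.152. The cytokine genes Il4 (0.14 ± 0.09), Il13 (-0.06 ± 0.11) and Il33 (-0.54 ± 0.22) did not pass.

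Mrgprg, Rnase2a, Smpd3 and Daglb rose in the flox/flox glands, and Retnla, Alox15, F5 and Muc16 had positive differences without passing. A strain haplotype around each of the 4 stays open: in 0 of 4 cases did the median absolute limma statistic of the 20 tested genes on each side lie above the 95th percentile of such windows, but a check added later showed that raising any 5 neighbours to the top would have brought 0 of the 4 there, so the test could not register a change in several genes. At an unadjusted p under 0.05 there were 6 of 38 neighbours for Mrgprg, near a chromosome end, 6 of 40 for Rnase2a, 4 of 40 for Smpd3 and 3 of 40 for Daglb, against 10.3% of all genes. Serosal cells in the flox/flox pieces are argued against, since 10 mesothelium genes had a median of -0.0197 and 7 peritoneal macrophage genes, 1 of them in the fixed macrophage list, -0.0134, while Alox15 was at 1.08 and Muc16 at 1.13; Upk3b, a mesothelial surface protein, read 173 in flox/flox and 164 in flox/+ glands, and Igfbp6, which fibroblasts express too, 1235 and 1403. An effect of the flox/flox genotype on cells that express these genes was not tested.

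Some clock-linked genes had positive differences without passing the test, among them Ciart (1.51 ± 0.24 SE, limma adjusted p = 0.0828), Usp2 (0.76 ± 0.11), Wee1 (0.74 ± 0.13) and Per2 (0.71 ± 0.14). Glands collected at another time of day may account for this, and 8 further outputs had a median of 0.345, 7 of them positive, from Hlf at 0.45 down to Nr1d1 at -0.25, with an exact permutation p of 0.0571 for their mean. The antiphase genes had a median of -0.108, Arntl at -0.57 but Nfil3 at 0.47, and the exact permutation p of the difference between the outputs and these was 0.143, which leaves the question open. Higher glucocorticoid exposure could raise Per2 as well as Fkbp5 (1.02) and Zbtb16 (0.96), but 10 other targets had a median of 0.103 (exact permutation p = 0.371 for their mean), with Tsc22d3 at 0.82 and Angptl4 at -0.50, and this too cannot be told apart from no shift. An effect of the flox/flox genotype on the clock was not tested.

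Probe sets with several symbols or none, 13768 in all, were tested once with all others in limma: 0 passed, the smallest adjusted p was 0.251 and 1333 had an unadjusted p under 0.05.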
